A study of Arabidopsis thaliana with 6 samples.

How the data were processed

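Leaves of 3-week-old Arabidopsis thaliana plants were profiled on 6 Affymetrix arrays, 3 for atpip1;2-1, a line with a T-DNA insertion, and 3 for the wild type N-60000, per the labels. The labels describe total RNA, biotin labelling, 5 plants pooled for each array and 15 plants for each line, and they call the arrays of a line biological replicates. Scan dates and hybridisation batches are not given in the sources used here, so no batch could be tested.

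The deposited values are log2 expression values, 1 per gene and array, named by AGI locus code. The submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes) and Partek, without versions or roles. How probes were grouped by AGI code, and which genome build or probe annotation was used, is not given in the sources used here. A second deposited table holds 1 value per probe set and array. Its scale and normalization are not given in the sources used here, and were taken as log2 and not centred from the range of its values and from their correlation with the table per gene, which lay between 0.960 and 0.966 over genes for the 6 arrays. Its array medians lay between 3.33 and 3.41, and those of the table per gene between 3.78 and 3.84. Because an RMA value depends on all probes assigned to a gene, a different assignment can give a different fold change for the same gene, and no value here was set against the value of another gene as an amount of transcript. The arrays carry no detection calls or background values in the tables used here, so dim genes were kept, and the number of arrays limits the precision.

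Each of the 28387 genes was tested for a difference between mutant and wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Fold changes are mutant minus wild type on the log2 scale. The difference of PIP1;2 was also tested with an exact permutation test over the splits of the 6 arrays. Groups of genes were tested with camera from limma at a preset correlation between genes of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over 32 lists. These lists hold 508 distinct genes, 507 of them measured, and were written from textbook knowledge of leaf biology before the data were examined, as were the tests, the threshold and most of the other settings tried. Camera with the correlation estimated from the arrays and fry, which tests a list by itself, were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. Genes near PIP1;2 were the 10 measured genes on each side in AGI order, set against all other windows of 20 genes on the 5 chromosomes.

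Genes to be named were chosen by a rule fixed beforehand: PIP1;2, the 10 highest and the 10 lowest log2 fold changes among genes past the threshold whose mutant and wild type arrays do not overlap, and from each list up to 4 members past the threshold or, where none passed, the 2 with the smallest unadjusted p. That rule took 77 genes. Other list members named in the text were chosen after their values were seen. Gene symbols came from a RefSeq gene table of assembly TAIR10.1, in which 27681 of the 28387 genes were found, and were otherwise those of the lists. No coordinates are given, since the build behind the deposited values is not given in the sources used here. Probe sets of the second table were named through the platform annotation: 16722 of its 38408 probe sets had 1 gene, 759 had several and 20927 had none here. Those with 1 AGI code were averaged per gene, which gave 16411 genes, 16315 of them also in the table per gene. PIP1;2 was not among them and was not analysed there.

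The other settings tried were the table per probe set, leaving out the dimmest 25% or 50% of genes, eBayes with a variance trend and robust fitting, array weights, quantile normalization applied again, equal array medians, a test without moderation of the spread, the replicate number as a block, each array left out in turn, other thresholds, the other list tests and 5 genes on each side of PIP1;2. A fit of 2 arrays against 2, and several gene groups described in the closing section, were added after the data were seen. The fits were tested on simulated data for the comparison of mutant and wild type: with 28387 simulated genes the limma fit recovered 0 of 67 genes changed 1.5-fold, 13 of 67 (19.4%) changed 2-fold and 63 of 66 (95.5%) changed 4-fold, and 5 of its 81 calls were unchanged genes. Camera recovered 5 of 5 lists shifted by 0.5 and called 0 others of 32, and with an estimated correlation it also recovered 5. The simulated genes varied independently and the lists held random genes. The simulation therefore cannot show how often camera at its preset correlation calls lists of correlated genes wrongly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.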

Results

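The data compared the leaf transcriptome of the Arabidopsis line atpip1;2-1, which carries a T-DNA insertion in the aquaporin gene PIP1;2, with that of the wild type. PIP1;2 is a plasma membrane intrinsic protein, a channel that has been studied for the passage of water and of carbon dioxide into leaf cells. There were 3 arrays for each line, each with RNA pooled from 5 plants at 3 weeks of age. The question put by the design was which leaf transcripts differ between the insertion line and the wild type. The table per gene held log2 values for 28387 genes, of which 130 are encoded in the chloroplast and 140 in the mitochondrion. Correlations between arrays over genes ranged from 0.975 to 0.989. With 3 arrays in each group, only large differences could be resolved: the median standard error of a log2 fold change was 0.19.

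PIP1;2 transcript was far lower in the insertion line. PIP1;2 (AT2G45960, listed as PIP1B in the reference table, on chromosome 2) had a log2 value of 8.87 ± 0.23 in the wild type and 5.28 ± 0.20 in the mutant (SD, n = 3), a log2 fold change of -3.59 (SE 0.18) or 12.0 times less. The single arrays gave 8.73, 9.14 and 8.74 in the wild type and 5.16, 5.51 and 5.18 in the mutant. The adjusted p from limma was 0.000148, the smallest of all genes, and the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Where the probes lie relative to the insertion is not given in the sources used here, and a probe upstream of it would not report the loss of a full transcript. Without moderation of the spread the adjusted p of PIP1;2 was 0.103.

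Beyond PIP1;2, the genes with the highest log2 fold changes in the mutant leaves included a plant defensin, a beta-1,3-glucanase and a calcium exchanger gene, and those with the lowest included 2 transcription factor genes of the ERF family. A total of 97 genes passed the threshold, 53 higher and 44 lower in the mutant, and in each of them the 3 mutant arrays lay on one side of the 3 wild type arrays. All 97 differed by more than 1.5-fold. Over all genes the groups did not overlap in 5262 genes (18.5%), where chance gives 10%, and 3476 genes (12.2%) had an unadjusted p under 0.05. Of the 97 genes, 89 are protein-coding nuclear genes in the reference table, 2 are small nucleolar RNA genes, 4 are chloroplast genes and 1 is a mitochondrial gene. The remaining gene, AT3G15536, is a non-coding RNA gene. Whether probes of nuclear genes also read transcripts of the chloroplast or mitochondrion was not tested.

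**Figure D1:**
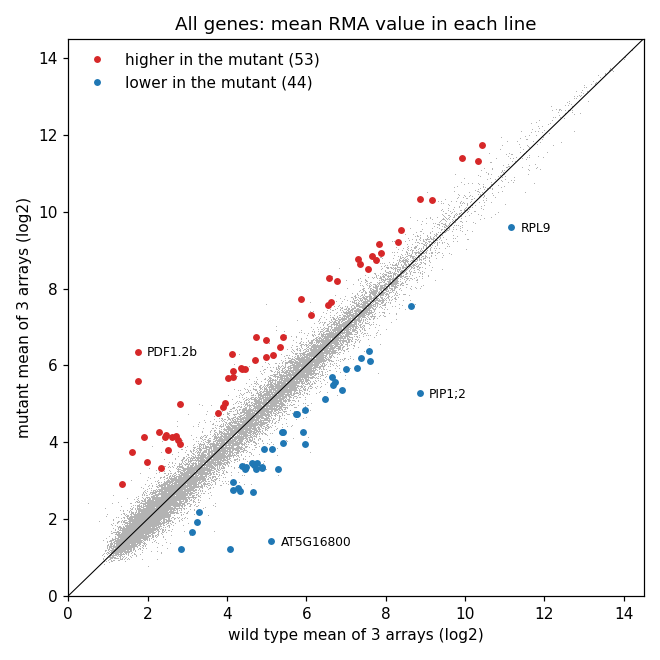
Mean log2 value of each gene over the 3 wild type arrays (horizontal axis) and the 3 mutant arrays (vertical axis), with the diagonal marking equal values. Red points are the 53 genes higher in the mutant and blue points the 44 genes lower, with PIP1;2 at 8.87 in the wild type and 5.28 in the mutant.

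The plant defensin gene PDF1.2b had the highest log2 fold change, 4.60 (SE 0.38, adjusted p = 0.00514), from 1.76 ± 0.33 to 6.36 ± 0.87 (SD, n = 3). Its wild type mean lay under the level that bounds the dimmest 25% of genes, as did the lower of the 2 group means of CML41, AT5G47970, AT5G53920, AT5G16800, AT3G42850 and AT1G35210. No background values show these means to be above background, so the sizes of the log2 fold changes of the 7 genes and their ranks are uncertain. For AT5G16800, AT3G42850 and AT5G53920 the probe-set table gave far smaller sizes (-0.57, -0.17 and 0.33). The defensin genes of this family are near-identical copies, so which copy the signal comes from is uncertain. AT4G16260, a beta-1,3-glucanase gene, rose by 2.17 (SE 0.20), and the vacuolar calcium and proton exchanger gene CAX3 also by 2.17 (SE 0.23), with adjusted p of 0.00569 and 0.00955. The calmodulin-like gene CML41 rose by 2.13 (SE 0.25, adjusted p = 0.0123). PYK10, the beta-glucosidase of endoplasmic reticulum bodies, rose by 2.01 (SE 0.19, adjusted p = 0.00569) from 4.73 ± 0.24 to 6.74 ± 0.21. The other genes of the 10 highest were AT5G47970 (3.83, SE 0.45), AT5G53920 (2.24, SE 0.35), MRD1 (1.96, SE 0.18), AT2G07678 (1.87, SE 0.19) and AT2G26120 (1.73, SE 0.21), with adjusted p between 0.00569 and 0.0328.

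Among the genes that fell, ERF6, a transcription factor gene of the ethylene response, had a log2 fold change of -1.98 (SE 0.21, adjusted p = 0.00955) and AT5G51190, another gene of the ERF family, of -1.59 (SE 0.22, adjusted p = 0.0219). LUP5, a gene of the triterpene synthase family, fell from 4.65 ± 0.18 to 2.70 ± 0.15, a log2 fold change of -1.95 (SE 0.17, adjusted p = 0.00569). RPL9, for a protein of the plastid ribosome, changed by -1.57 (SE 0.16, adjusted p = 0.00955). The other genes of the 10 lowest were AT5G16800 (-3.70, SE 0.53), AT3G42850 (-2.84, SE 0.32), the DNA topoisomerase gene TOPII (-2.02, SE 0.23), AT2G24600 (-1.65, SE 0.19) and AT1G35210 (-1.62, SE 0.20), with adjusted p between 0.0105 and 0.0242.

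**Figure D2:**
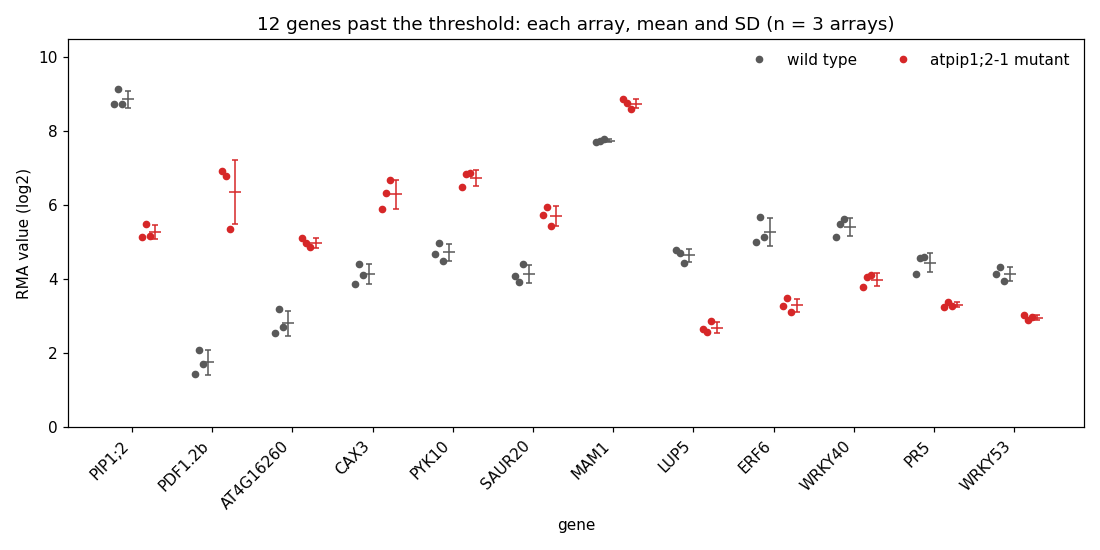
Log2 values of 12 genes past the threshold on each array, grey for the wild type and red for the mutant, with the mean and SD of 3 arrays beside the points. PIP1;2 fell from 8.87 to 5.28, PDF1.2b rose from 1.76 to 6.36, and in all 12 genes the arrays of the 2 lines do not overlap.

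The probe-set table measured 44 of the 97 genes, 43 of them with the same direction and 22 past the threshold there. Those 22 passed in a fit adjusted over its 16411 named genes alone. When all 38408 probe sets were tested together, 3 passed, 1 higher and 2 lower in the mutant. Of the 44 genes, 13 had a size smaller by over 1.5 times in the probe-set table: AT5G16800 had -0.57 in place of -3.70, AT3G42850 -0.17 in place of -2.84, TOPII -0.04 in place of -2.02, AT5G53920 0.33 in place of 2.24 and AT2G07678 1.12 in place of 1.87, while AT5G65220 had -0.21 in place of 1.05. PDF1.2b (3.83), CML41 (2.21), AT4G16260 (2.34), PYK10 (1.60) and LUP5 (-2.03) lay closer to their values per gene. Leaving out 1 array gave 22, 35 or 24 genes past the threshold without mutant replicate 1, 2 or 3, and 38, 14 or 48 without wild type replicate 1, 2 or 3. The 9 genes past the threshold without each array in turn were PIP1;2, PDF1.2b, AT4G16260, CAX3, PYK10, MRD1, AT2G07678, LUP5 and DR4 (1.70), the last named after its values were seen. Without moderation of the spread, 0 genes passed with limma's linear fit, and 3076 had an unadjusted p under 0.05.

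Of the 32 gene lists, 9 moved one way as groups by camera with its preset correlation, and 0 passed with an estimated correlation (6 at an unadjusted p under 0.05). Of the 9, aliphatic glucosinolate synthesis, auxin response, the abscisic acid and dehydration response, light harvesting, the Calvin-Benson cycle, iron deficiency and sulfur limitation were higher in the mutant, and the rapid stress response and salicylic acid defence were lower. By fry, which asks whether a list moves one way on balance, 9 lists passed: 8 of these and anthocyanin and flavonoid synthesis (adjusted p = 0.0244), while the Calvin-Benson cycle did not (adjusted p = 0.0534). Fry's other test, for change in either direction without comparing a list with other genes, passed 18 lists, the 9 called by camera and 9 others (adjusted p from 1.45e-06 to 0.0191): jasmonate and wounding, leaf senescence, vascular markers, epidermis and wax markers, sugar starvation, carbonic anhydrases, the circadian clock, its evening genes and phosphate starvation. The probe-set table named 72 of the 507 measured members. There 1 list passed, the rapid response, on 1 named member.

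**Figure D3:**
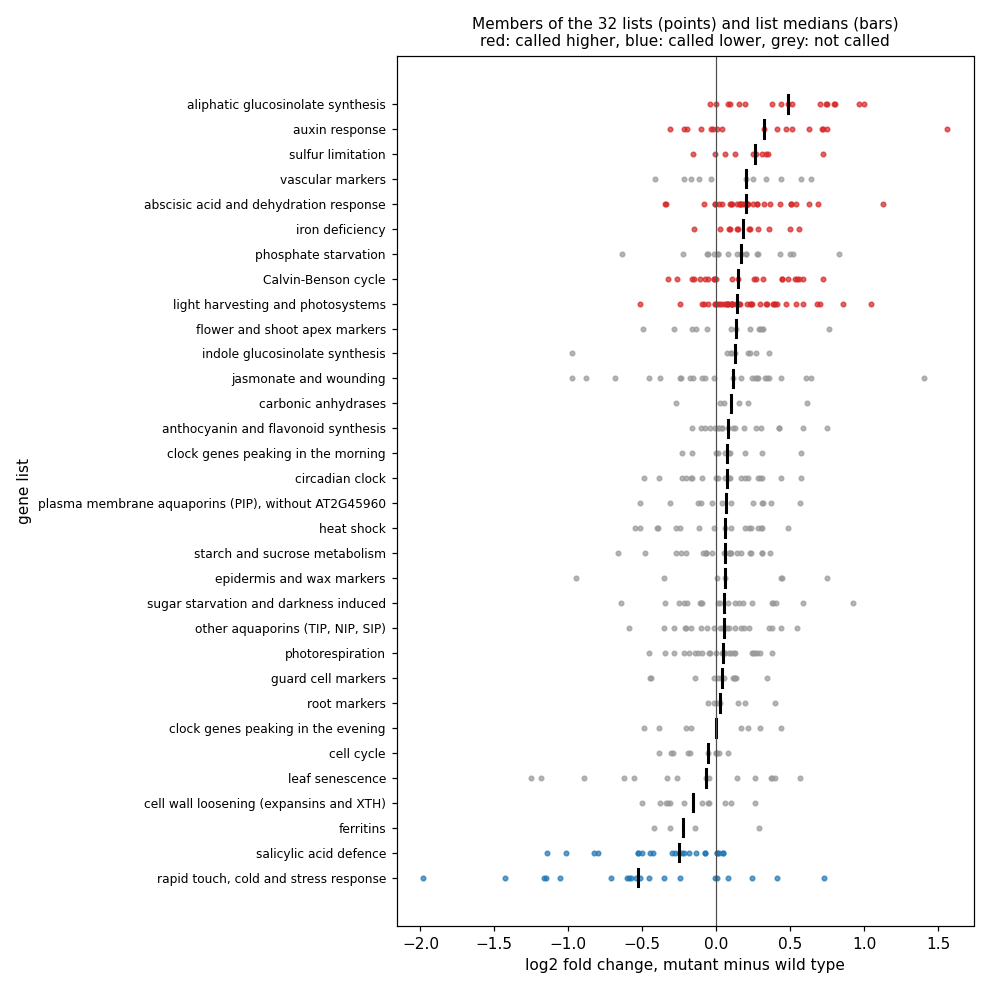
Log2 fold change, mutant minus wild type, of each measured member of the 32 lists (points) with the list medians (black bars). The 7 lists called higher by camera are red, the 2 called lower are blue and the others grey, and the medians run from -0.53 for the rapid response to 0.48 for aliphatic glucosinolate synthesis.

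Genes of aliphatic glucosinolate synthesis, which make methionine-derived defence compounds, had a median log2 fold change of 0.48, with 15 of 17 measured members higher in the mean (adjusted p = 1.67e-08; adjusted p = 0.0643 with an estimated correlation). MAM1, the methylthioalkylmalate synthase that lengthens the side chain, rose by 1.00 (SE 0.15, adjusted p = 0.0317) from 7.75 ± 0.04 to 8.75 ± 0.13 (SD, n = 3). It was the 1 member past the threshold over all genes, and 16 did not pass. When adjusted over the list alone, 10 members passed, all higher, among them BCAT4 (0.96), CYP83A1 (0.80) and the regulator genes MYB28 (0.48) and MYB29 (0.44). CYP79F1 (0.80) and CYP79F2 (0.74) are near-identical copies, so their separate values are uncertain. AOP2 was not analysed here.

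The auxin response list had a median of 0.32, with 11 of 17 members higher (adjusted p = 0.00106; adjusted p = 0.103 with an estimated correlation). SAUR20, a small auxin up RNA gene, rose by 1.56 (SE 0.20, adjusted p = 0.0172), and the other 16 members did not pass over all genes. A total of 6 members passed adjusted over the list alone, all higher, including SAUR21 (0.75), SAUR24 (0.72) and IAA1 (0.63). The SAUR19 to SAUR24 genes are near-identical neighbours, so the values of single members are uncertain, and 5 of the 6 come from that cluster. In the probe-set table, where 5 of the 17 members were named, the list's direction was down with an adjusted p of 0.861.

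Genes of the abscisic acid and dehydration response had a median of 0.20, with 29 of 34 members higher (adjusted p = 0.000137; adjusted p = 0.0643 with an estimated correlation). KIN2, a gene of the cold and dehydration response with a near-identical copy, rose by 1.13 (SE 0.16, adjusted p = 0.0243), and had 0.74 in the probe-set table. The other 33 did not pass over all genes. There were 2 that passed adjusted over the list alone, both higher: KIN2 and ERD1 (0.69), which codes for a chloroplast protease subunit.

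The light harvesting and photosystem genes shifted by a small amount, with a median of 0.14 and 34 of 41 members higher (adjusted p = 6.83e-05; adjusted p = 0.214 with an estimated correlation). None of the 41 passed over all genes with limma (11 at an unadjusted p under 0.05), and 4 passed adjusted over the list alone, all higher: LHCA1 (1.05, SE 0.23), LHCB1.3 (0.68, SE 0.16), LHCB1.2 (0.86) and LHCB1.5 (0.70). The LHCB1 genes are near-identical copies and their single values are uncertain. The Calvin-Benson cycle list had a median of 0.15, with 14 of 23 members higher (adjusted p = 0.0309; adjusted p = 0.214 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05). GAPA2 had 0.72 (SE 0.22, adjusted p = 0.242) and CP12-1 had 0.59 (SE 0.19, adjusted p = 0.261).

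Iron deficiency genes had a median of 0.18, with 11 of 12 members higher (adjusted p = 0.0200; adjusted p = 0.212 with an estimated correlation). None passed over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05). IMA2, a peptide gene of the iron deficiency response, had 0.56 (SE 0.17, adjusted p = 0.243), and the transcription factor gene BHLH38 had 0.50 (SE 0.19, adjusted p = 0.346). Sulfur limitation genes had a median of 0.26, with 8 of 10 members higher (adjusted p = 0.0319; adjusted p = 0.214 with an estimated correlation). None passed over all genes (1 at an unadjusted p under 0.05), and adjusted over the list alone 1 did: APR1, an enzyme gene of sulfate reduction, with 0.72 (SE 0.17), while APR2 had 0.33 (SE 0.16). The calls of the Calvin-Benson cycle, iron deficiency and sulfur limitation held in 9, 12 and 10 of 18 alternatives: without mutant replicate 1 their adjusted p were 0.133, 0.0718 and 0.123. Without wild type replicate 1 they ended for the Calvin-Benson cycle (0.0849) and sulfur limitation (0.0687), without wild type replicate 3 for the Calvin-Benson cycle (0.0856) and iron deficiency (0.0637), and without mutant replicate 3 (0.0621) or wild type replicate 2 (0.0839) for sulfur limitation. The call of the Calvin-Benson cycle also ended with quantile normalization again (0.337), with the dimmest 25% or 50% of genes left out (0.0559 and 0.129) and by fry, that of iron deficiency with quantile normalization again (0.0798) and that of sulfur limitation with the dimmest 25% left out (0.0638). With 2 arrays against 2, a fit chosen after seeing the data, those of iron deficiency (0.0538) and sulfur limitation (0.0532) ended, and in the probe-set table all 3 (0.939 for the Calvin-Benson cycle, 0.167 for iron deficiency and 0.599 for sulfur limitation).

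Genes of the rapid response to touch, cold and stress were lower in the mutant, with a median of -0.53 and 15 of 20 members lower (adjusted p = 3.16e-05; adjusted p = 0.0643 with an estimated correlation). Over all genes 4 members fell and 16 did not pass. ERF6 changed by -1.98, WRKY40, a transcription factor gene of the defence response, by -1.43 (SE 0.18, adjusted p = 0.0184), the zinc finger gene ZAT10, listed as STZ in the reference table, by -1.17 (SE 0.20, adjusted p = 0.0491) and SZF1 by -1.15 (SE 0.17, adjusted p = 0.0261). Adjusted over the list alone 6 were lower, with ERF104 (-1.06) and the cell wall enzyme gene TCH4 (-0.71) added, and 1 was higher, the cold response regulator CBF2 (0.73).

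Salicylic acid defence genes were lower as well, with a median of -0.25 and 18 of 23 members lower (adjusted p = 6.83e-05; adjusted p = 0.0643 with an estimated correlation). PR5, a pathogenesis-related gene, changed by -1.14 (SE 0.18, adjusted p = 0.0318) from 4.45 ± 0.26 to 3.31 ± 0.07 (SD, n = 3), and 22 members did not pass over all genes. Adjusted over the list alone 5 passed, all lower, including the regulator gene SARD1 (-1.02), PR1 (-0.83) and WRKY38 (-0.80).

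Other aquaporin genes and the carbonic anhydrases did not move one way as groups. Of the 12 PIP genes besides PIP1;2 none passed over all genes or adjusted over the list alone, called either way in what follows, and 1 had an unadjusted p under 0.05 (median 0.07, adjusted p = 0.481). PIP2;1 had 0.57 (SE 0.21, adjusted p = 0.313) and PIP2;2 had 0.37 (SE 0.18, adjusted p = 0.433). None of the 22 TIP, NIP and SIP genes passed either way and 4 had an unadjusted p under 0.05 (median 0.05, adjusted p = 0.673), with -0.59 (SE 0.19, adjusted p = 0.257) for TIP1;1 and 0.44 (SE 0.16, adjusted p = 0.310) for NIP5;1. None of the 6 carbonic anhydrase genes passed over all genes and 1 had an unadjusted p under 0.05 (median 0.10, adjusted p = 0.424). That gene, CA6, passed adjusted over the list alone, with 0.61 (SE 0.18), and CA5 had -0.27 (SE 0.16). Differences of the size measured here, below 2-fold, lay under what 3 arrays against 3 resolved in simulated data.

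Genes of carbon metabolism other than the Calvin-Benson cycle did not move one way as groups. None of 26 photorespiration genes passed either way and 1 had an unadjusted p under 0.05 (median 0.05, adjusted p = 0.673), with -0.45 (SE 0.20) for GS2 and -0.35 (SE 0.17) for GOX2. None of 23 starch and sucrose genes passed either way and 1 had an unadjusted p under 0.05 (median 0.06, adjusted p = 0.690), with -0.67 (SE 0.21) for BAM5 and -0.48 (SE 0.23) for GPT2. Of 20 genes induced by sugar starvation and darkness none passed over all genes (2 unadjusted) and 1 passed adjusted over the list alone, the asparagine synthetase gene ASN1 (0.93, SE 0.18, adjusted p = 0.0871 over all genes), while TPS8 had 0.59 (SE 0.19) and the list did not pass (median 0.05, adjusted p = 0.383).

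Hormone, stress and nutrient lists that did not pass with camera held members that went both ways. The 25 jasmonate and wounding genes had a median of 0.11 (adjusted p = 0.528) with none past the threshold over all genes and 8 at an unadjusted p under 0.05. Of these, 2 were higher adjusted over the list alone, the defensin gene PDF1.2A (1.41) and AOS (0.61), and 3 were lower, LOX4 (-0.98), CYP94B3 (-0.88) and LOX3 (-0.68). None of 17 heat shock genes passed either way and 1 had an unadjusted p under 0.05 (adjusted p = 0.951), with -0.51 (SE 0.17) for HSA32 and -0.40 (SE 0.20) for HSFA2, and the list's median of 0.06 differed in sign from its mean of -0.02 and from the test. In leaf senescence WRKY53, a transcription factor gene, fell with -1.19 (SE 0.16, adjusted p = 0.0219) and the other 14 genes did not pass over all genes, while adjusted over the list alone 3 were lower and 1 was higher (median -0.07, adjusted p = 0.230). Of 19 anthocyanin and flavonoid genes none passed over all genes (2 unadjusted) and 1 passed adjusted over the list alone, the regulator gene PAP1 (0.75, SE 0.16), while LDOX had 0.59 (SE 0.23, list median 0.08, adjusted p = 0.0747). That list passed in 3 of 18 alternatives (adjusted p from 0.0244 to 0.857 over all): without wild type replicate 3 (0.0405), with 2 arrays against 2 (0.0457) and by fry. Of 9 indole glucosinolate genes none passed over all genes (1 unadjusted) and 1 was lower adjusted over the list alone, the regulator gene MYB51 (-0.97, SE 0.19, adjusted p = 0.0872 over all genes), while CYP83B1 had 0.36 (SE 0.19, list median 0.13, adjusted p = 0.481). None of 19 phosphate starvation genes passed either way and 4 did unadjusted (median 0.17, adjusted p = 0.0769), with 0.83 (SE 0.24) for SQD1 and 0.52 (SE 0.15) for SPX3. The phosphate list passed in 4 of 17 alternatives (adjusted p from 0.0223 to 0.214 over all): with array weights (0.0310), without mutant replicate 3 (0.0377), without wild type replicate 3 (0.0405) and with 2 arrays against 2 (0.0223). None of 4 ferritin genes passed either way, nor unadjusted (median -0.23, adjusted p = 0.636), with -0.42 (SE 0.22) for FER3 and 0.29 (SE 0.16) for FER2.

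Clock and growth lists did not pass with camera. None of the 20 circadian clock genes passed over all genes or adjusted over the list alone and 2 had an unadjusted p under 0.05 (median 0.07, adjusted p = 0.618), with -0.49 (SE 0.15, adjusted p = 0.236) for TOC1 and 0.58 (SE 0.23) for LNK3. The 10 clock genes that peak in the morning had a median of 0.07 (adjusted p = 0.430) with 0.31 (SE 0.17) for LHY, and the 8 that peak in the evening a median of -0.000917 (adjusted p = 0.829) with -0.39 (SE 0.22) for ELF4, none of them past the threshold either way and 1 of each unadjusted. None of 12 expansin and XTH genes of cell wall loosening passed either way and 2 did unadjusted (median -0.16, adjusted p = 0.190), with -0.51 (SE 0.21) for XTH9 and -0.38 (SE 0.17) for EXPA10. None of 11 cell cycle genes passed either way, nor unadjusted (median -0.06, adjusted p = 0.424), with -0.39 (SE 0.22) for CDKB1;1 and -0.30 (SE 0.23) for CYCA1;1.

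Markers of the cell types and organs that a leaf sample can hold did not shift one way as groups. None of 12 guard cell markers passed either way and 1 did unadjusted (adjusted p = 0.896), with -0.44 (SE 0.16) for ALMT12 and 0.34 (SE 0.17) for SLAC1, and the list's median of 0.04 and its mean of -0.01 differed in sign. None of 11 vascular markers passed either way and 4 did unadjusted (median 0.20, adjusted p = 0.287), with 0.64 (SE 0.18) for the sucrose exporter gene SWEET11 and 0.58 (SE 0.19) for SWEET12. Among 7 epidermis and wax markers CER1, a gene of wax alkane synthesis, fell with -0.95 (SE 0.16, adjusted p = 0.0491) and 6 did not pass over all genes. Adjusted over the list alone 1 was lower and 3 were higher, among them KCS6 (0.75), and the list did not pass (median 0.06, adjusted p = 0.528). None of 7 root markers passed either way and 1 did unadjusted (median 0.03, adjusted p = 0.424), with 0.40 (SE 0.17) for FRO2 and 0.19 (SE 0.19) for EXPA18. Of 13 flower and shoot apex markers none passed over all genes (2 unadjusted) and 1 passed adjusted over the list alone, the flowering regulator SOC1 (0.76, SE 0.19), while AP3 had -0.50 (SE 0.19, list median 0.13, adjusted p = 0.416).

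Genes next to PIP1;2 on chromosome 2 showed no call. None of the 10 measured genes on each side of PIP1;2 passed the threshold with limma, and 3 of these 20 had an unadjusted p under 0.05. Of 28016 other windows of 20 genes on the 5 chromosomes, 6.24% held a gene past the threshold and the highest held 3.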

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

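The test of all probe sets of the second deposited table was fixed before the data were examined, and its unnamed probe sets were singled out only after the result was seen. Of the 20927 probe sets in that table with no gene name here, 2 passed the adjusted threshold when all 38408 probe sets were tested with limma, a signal in probe sets that the comparison of genes did not use by name. Probe set 13405574 fell from 6.81 ± 0.10 in the wild type to 3.31 ± 0.03 in the mutant (SD, n = 3), a log2 fold change of -3.50 (SE 0.12, adjusted p = 0.00178). Probe set 13545469 rose from 3.53 ± 0.21 to 8.49 ± 0.31 (SD, n = 3), a log2 fold change of 4.95 (SE 0.20, adjusted p = 0.00284). Which genes they read, and whether these are among the genes compared above, was not tested; PIP1;2 has no named probe set here.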

How the results depend on the processing

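All settings here were planned, except the fit of 2 arrays against 2, chosen after seeing the data. PIP1;2 kept its direction in 15 alternatives (-3.70 to -3.45) and passed in 14 of them; without moderation it was -3.59 with an adjusted p of 0.103. Of the 97 genes, PIP1;2 included, all that were tested kept their direction in every alternative on the table per gene. Leaving out or weighting arrays could not have turned a direction, since the arrays of the 2 lines do not overlap in these genes. Leaving out dim genes, the variance trend, no moderation and the replicate block do not change a fold change. Only quantile normalization again and equal medians could have turned a direction. Against 53 genes higher, 44 lower and 9 lists, the 16411 named genes of the probe-set table gave 16, 15 and 1 (22 of the 31 genes shared). Fewer genes were named there, and with all 38408 probe sets tested together 3 passed. The auxin response list turned down in the probe-set table (camera adjusted p = 0.861, 5 of 17 members named). Leaving out the dimmest 50% gave 106 and 90, with fewer genes tested. A variance trend with robust fitting gave 216 and 159, all 97 among them, and no moderation gave 0 and 0 (3076 unadjusted); the cause was not tested. With fewer arrays, leaving out each array gave 10 to 22 higher, 4 to 26 lower and 6 to 9 lists, and 2 arrays against 2 (without mutant and wild type replicate 3, those of lowest array weight, 0.640 and 0.617) gave 1 and 1, and 9 lists. Looser thresholds gave 102 and 89 (adjusted p under 0.1) and 756 and 790 (unadjusted p under 0.05 and 1.5-fold). Camera with an estimated correlation called 0 lists (6 unadjusted), fry 9. The replicate block gave 23 and 22 and 9 lists, 43 of its 45 genes among the 97, and the cause was not tested. Arrays of the 2 lines with the same replicate number had residual correlations of 0.0085, 0.0498 and 0.0745. Other pairs between the lines had -0.0802 to 0.0471. These correlations are small, but an effect shared by a replicate number is not excluded. On the second principal component, an axis of variation among the arrays, replicate 3 lay at -16.4 in the mutant and -42.2 in the wild type. The other arrays lay between 6.75 and 19.9. The dimmest 25% left out, array weights, quantile normalization again, equal medians (64 and 39) and the 1.5-fold minimum kept the counts within 1.5 times, as did 5 genes on each side of PIP1;2 (0). Of 1129 values of single genes under alternatives 957 kept their side of the threshold, 156 fell below it and 16 rose past it. Of 568 of lists 527 kept it, 33 fell below it, 7 rose past it and 1 turned direction. Signal over background is not given in the tables used here.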

Other observations

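The gene groups and the tests in this part were chosen only after the genes past the threshold were seen, except that for the organelle genes and the rapid response the tests of the median without single arrays, and for neighbouring genes the test of overlap, were written before their results. Genes of DNA replication were lower in the mutant: all 12 members of a list of helicase, clamp and licensing genes with TOPII and VIM1 were lower in the mean, with a median log2 fold change of -0.75. Of these 4 passed the threshold over all genes, the helicase subunit genes MCM3 (-1.12, SE 0.17) and MCM6 (-1.10, SE 0.17), the DNA methylation factor gene VIM1 (-1.18, SE 0.18) and TOPII (-2.02, SE 0.23), though TOPII had -0.04 in the probe-set table. Camera, adjusted over 4 such groups, gave an adjusted p of 2.13e-14, and an adjusted p of 0.0114 with an estimated correlation. Because the genes past the threshold led to this group, it was tested again without them, and the other 8 members had a median of -0.58, all lower (camera unadjusted p = 1.51e-07, and 0.0229 with an estimated correlation). These 8 were also chosen after the genes past the threshold were seen, so the second test is not independent of that choice. The cell cycle list fixed beforehand did not pass (adjusted p = 0.424).

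Genes of endoplasmic reticulum bodies and of the PYK10 complex, a store of beta-glucosidase and its binding lectins that acts when tissue is wounded, were higher in the mutant. Of 17 members 13 were higher in the mean, with a median of 0.56, and 5 passed the threshold over all genes: PYK10 (2.01, SE 0.19), AT3G16420 (1.53, SE 0.22), NAI2 (1.46, SE 0.19), JAL23 (1.45, SE 0.22) and TSA1 (1.25, SE 0.20). NAI2 and JAL23 had 1.36 and 1.36 in the probe-set table. Camera gave an adjusted p of 2.16e-10 for the group, and an adjusted p of 0.0172 with an estimated correlation. Without those 5 genes 8 of 12 members were higher, with a median of 0.40 (camera p = 0.00140; p = 0.125 with an estimated correlation), so the group rests in large part on the genes that led to it.

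Genes encoded in the organelles were higher in the mutant, with a median log2 fold change of 0.26 over 270 genes (95% resampling interval 0.23 to 0.30), 0.15 over the 130 chloroplast genes and 0.37 over the 140 mitochondrial genes, of which 126 were higher; with an estimated correlation the adjusted p were 0.134 and 0.0609. The mitochondrial genes, with a median level of 7.96, stood at percentile 100 of 10000 lists of nuclear genes matched on level, whose 95th percentile was 0.07. At levels that nuclear genes share, this argues against a shift of all genes at that signal level from the normalization. Matching used 20 bins of level, and the chloroplast genes had a median level of 12.44. They were set against mostly dimmer nuclear genes of the top bin, so for them the test cannot decide. A single array as the whole source is argued against by the lowest median with 1 array left out, 0.18 without mutant replicate 3 (interval 0.16 to 0.22). The resampling intervals here and below draw the genes of a group and not arrays, so they do not measure the spread between arrays. A larger share of RNA without poly(A) tails on the mutant arrays stays open, since the 508 nuclear genes for small nucleolar, small nuclear, transfer and ribosomal RNA also stood at percentile 100 of their matched lists, though with a smaller median of 0.06 (interval 0.03 to 0.10): 0.38 (0.11 to 0.51) for 71 small nucleolar, 0.03 (0.02 to 0.06) for 423 transfer, 0.06 (-0.09 to 0.35) for 10 small nuclear and 0.08 (-0.03 to 0.18) for 4 ribosomal RNA genes, 2 higher and 2 lower. A difference in organelle transcripts that comes from the insertion line itself stays open and was not tested.

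The lower rapid response to touch, cold and stress could come from plants handled or harvested differently, which the labels do not record and which was not tested. A different time of day at harvest stays open: the clock genes had a median size of log2 fold change of 0.20 (95% resampling interval 0.13 to 0.29), at percentile 64.6 of matched nuclear lists, against 0.56 (interval 0.38 to 0.72) for the rapid response genes, but fry's test for change in either direction passed for the clock list (adjusted p = 0.0141) and its evening genes (adjusted p = 0.0115), and TOC1 had -0.49 with arrays of the lines that did not overlap. A single array as the whole cause is argued against: without each array in turn the list's median lay between -0.54 and -0.41, against -0.53 with all, and camera at its preset correlation gave an adjusted p of at most 0.000359, without mutant replicate 1, though with an estimated correlation the list did not pass with all 6 arrays (adjusted p = 0.0643) or without any 1 (adjusted p from 0.145 to 0.231, unadjusted from 0.0119 to 0.0301). How much of the size that array adds stays open, since the median without it, -0.41, has an interval of -0.70 to -0.14. An effect of the lower PIP1;2 transcript, or of any other difference between the single insertion line and the wild type, stays open as a hypothesis and was not tested.

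Some genes past the threshold lay side by side on the chromosomes. By a rule set after these genes were seen, there were 3 pairs that changed the same way with at most 1 measured gene between them, MRD1 and HEI10 (1.96 and 1.45), AT4G31354 and AT4G31355 (1.47 and 1.02), and AT4G16240 and AT4G16260 (1.14 and 2.17). Random placement of the called genes gave a permutation p of 0.0039 for 3 pairs, which decides nothing about chance, since the rule was set after they were seen. Overlapping gene models read by the same probes could explain the first and second pair, whose genes overlap in the reference annotation, but not the third, the 1 pair without overlap. For that pair chance stays open, since 2383 of 10000 placements gave at least 1 pair without overlap (permutation p = 0.238), and probes shared between related genes or a local difference between the lines were not tested.

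The counts of the report were also taken over the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. Each of the other splits also mixes arrays of both lines in both groups. A difference between the lines then adds to the spread within groups and can lower the counts, so these do not show what chance gives. The real split gave 53 genes higher, 44 lower and 9 lists, and the highest of the other splits gave 0, 0 and 3, with limma and camera and with up to 1781 genes at an unadjusted p under 0.05; 1 split, the real one, reached each real value.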
